A study of Homo sapiens with 8 samples.

How the data were processed

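Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate the binding sites of transcription factors in 2 human epithelial cancer cell lines, DU145 from prostate and PANC1 from pancreas. The series has 8 samples in 8 groups, with 1 sample per group. In DU145 the immunoprecipitated factors were ETS1, ELF1, ELK4, GABPA and JUND, and in PANC1 the factor was ETS1. Each line also has an input sample, and the 2 inputs were not used here because no processed file of theirs was at hand. The labels give no replicates for any factor, so p-values and intervals below describe the peaks of these lists and not the variation between cultures.

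The 7 deposited files are peak lists with 3 columns, namely the chromosome, the start and the end of each interval. Per the labels, the genome build is hg19, and the submitters' processing notes name Bowtie2 2.0.6 without saying what it was used for. The peak caller, its threshold, the use of the inputs as background and the number of reads behind each list are not given in the sources used here. The files hold no score, fold or count per peak, so the depth of each sample is unknown and peaks could be ranked only by width or by line order. The DU145 ETS1 sample has 2 lists. One of them is marked R2, but the labels do not say whether they come from separate immunoprecipitations, so they were counted as 1 sample.

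Interval width differed between the deposited lists. The first ETS1 list and the JUND list hold regions of varying length, with medians of 1173 and 696 bp. The other 5 lists hold windows with medians between 495 and 497 bp. Widths within these 5 lists are nearly uniform, so a ranking by width there carries little information. A wide interval meets another list more easily than a narrow one. Line order of the ETS1 lists also carried information that no source explains. Over the 8183 peaks of the first ETS1 list that overlap the second, Spearman's rho of the line numbers was 0.853. It is a correlation across peaks, which are not independent replicates. Between the second ETS1 list and the lists of other factors, rho was 0.305 for GABPA, 0.108 for ELF1, -0.052 for ELK4 and -0.086 for JUND. The PANC1 list is grouped by chromosome, so it was never shortened by line order.

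Intervals were compared with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with Matplotlib 3.10.9. Peaks that share at least 1 bp were counted as overlapping. ETS1 regions are the merged intervals of overlapping peaks that hold at least 1 peak of each DU145 ETS1 list. Shares carry 95% Clopper-Pearson intervals, which cover counting error only. Each share was compared by permutation of peak positions, with 1000 random placements of the same intervals on the same chromosomes, within the span that the lists cover, and the smallest p that these placements can give is 0.001. Placements ignore that binding sites and mappable sequence are clustered, so the random share is a low baseline. Shares of 2 sets of peaks were compared with Fisher's exact test, two-sided, with the conditional odds ratio and its exact 95% interval. The p-values were adjusted by the Benjamini-Hochberg method over the 11 such tests. Where a whole list is compared with ETS1 regions, many of its peaks lie in those regions, so the same sites stand in both rows. The rows are then not independent, and the p-values and intervals of those tests are approximate. Associations within 5 equal groups of ETS1 regions by line order were pooled as Mantel-Haenszel odds ratios, with approximate 95% intervals. For a share of 0, the limit given is a floor of 3 counts of the total.

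The overlap and odds ratio steps were tested on simulated data. The overlap was recovered in 3 of 3 simulated lists. Of 100 simulated tables each, 97 intervals held a true odds ratio of 0.5, 97 held 1 and 94 held 6. These tables had independent rows, so they do not cover tests in which a site stands in both rows. Of 60 pairs of unrelated simulated lists, the placement test, run with fewer placements, called 0 at a threshold of 0.05. These lists were spread evenly along chromosomes, so they do not show how the test behaves for clustered peaks.

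Before the data were examined, 10 alternatives were fixed. They were an overlap of at least 50% of the shorter interval, peak centres within 200 bp, intervals within 500 bp, the wider peaks of every list, the lists of each comparison shortened by width to the shortest among them (for a share, the shorter of the 2), the first or the second ETS1 list alone, the union of both, merging of peaks under 5 kb apart, and random placements shifted by 10 to 100 kb. A further 6 were chosen after seeing the data. They were intervals of 500 bp around each centre, the earlier lines of every list up to its midpoint, the lists of each comparison shortened in the same way by line order, the second ETS1 list shortened by line order to the length of the list it is compared with, leaving out chromosome 6, and the pooling within 5 equal groups by line order. The named regions follow a rule fixed before the data were examined. It asks for the 5 peaks of each list with the highest score, for which width stood in because the files give none, with ties taken in line order, and for the widest ETS1 regions of 4 overlap classes. Only part of the regions chosen by that rule are printed.

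No genome sequence or gene annotation of hg19 was used here. The planned share of peaks at promoters, the sequence motifs within peaks, the fixed gene lists near peaks and the placements matched on distance to a transcription start site were therefore not run, and no gene names are attached to peaks.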

Results

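ChIP-seq peak lists were compared for 5 transcription factors in DU145 prostate cancer cells and for 1 of them, ETS1, in PANC1 pancreatic cancer cells. ETS1, ELF1, ELK4 and GABPA belong to the ETS family, whose members share a DNA-binding domain that recognises sites with a GGAA core. ELK4 is also a partner of serum response factor, and JUND is a member of the AP-1 family. The title of the series places ETS1 downstream of RAS/ERK signalling in epithelial cells. The lists bear on how far ETS1 sites are shared with other ETS factors, with an AP-1 factor and with a second cell line. There was 1 sample per factor and line, and the labels name no biological replicate.

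ETS1 had by far the most peaks in DU145. Its first list held 9984 and its second 9306, against 2478 for GABPA, 1308 for JUND, 337 for ELK4 and 256 for ELF1. The PANC1 ETS1 list held 409 peaks. The number of reads behind each list is unknown, so these counts do not compare binding between factors or lines.

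The 2 DU145 ETS1 lists were compared first, since every later comparison rests on them. Of the first list, 82.0% (95% Clopper-Pearson interval 81.2 to 82.7%, 8183 of 9984) overlapped the second. Of the second list, 88.4% (87.7 to 89.0%, 8224 of 9306) overlapped the first. Random placements on the same chromosomes gave means of 0.778% and 0.832%, and no placement reached the observed share (permutation of peak positions, p = 0.001, the smallest that 1000 placements can give). The 8183 ETS1 regions present in both lists had a median width of 1273 bp. The widest, on chromosome 11 from 65184646 to 65198352 (hg19), held a JUND peak and a PANC1 ETS1 peak. The next widest peak of the first list, on chromosome 17 from 27044032 to 27056104, spanned 12073 bp and held a PANC1 ETS1 peak but no JUND peak.

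The next question was how many sites of the other ETS factors coincide with ETS1. Nearly all GABPA peaks did, at 93.1% (92.0 to 94.1%, 2307 of 2478), followed by ELF1 at 89.1% (84.6 to 92.6%, 228 of 256) and ELK4 at 79.2% (74.5 to 83.4%, 267 of 337). In this setting the ELK4 interval lies below those of GABPA and ELF1. Random placements gave means between 0.779% and 0.808% for these lists (permutation p = 0.001 each, the smallest the placements can give). In the other direction, 28.1% of ETS1 regions (27.2 to 29.1%, 2302 of 8183) held a GABPA peak, 3.25% (2.88 to 3.66%) an ELK4 peak and 2.79% (2.44 to 3.17%) an ELF1 peak. With peak centres within 200 bp, the share of ELK4 peaks at ETS1 regions was 52.2%. With lists shortened by width, at different lengths, ELK4 (8.31%) lay above ELF1 (2.34%) and below GABPA (33.2%). Among the wider peaks the intervals overlapped, with 48.4% for ELF1, 44.4% for ELK4 and 47.2% for GABPA. The reverse shares follow the lengths of the lists, because a list of 256 peaks can meet only a small part of 8183 regions. At least 1 of the 3 factors was present at 30.4% of ETS1 regions (29.4 to 31.4%).

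Within ETS1 regions the other ETS factors occurred together more often than independent lists would. ELK4 and GABPA shared 169 ETS1 regions where 74.8 would follow from independence (odds ratio 4.72, 95% interval 3.64 to 6.16, Fisher's exact test, two-sided, adjusted p = 2.55e-33 over 10 pairs of lists). ELF1 and GABPA shared 134 against 64.1 (odds ratio 3.80, 2.89 to 5.03), and ELF1 and ELK4 shared 26 against 7.41 (4.14, 2.59 to 6.39). All 3 lists favour the earlier lines of the ETS1 list, and pooled within 5 equal groups by line order, a setting chosen after seeing the data, the odds ratios were 3.68, 2.56 and 2.88 in the same order. All 3 were present at 22 regions. The widest of these lay on chromosome 14 from 50099689 to 50102615, and it was the single region that also held both a JUND and a PANC1 ETS1 peak. Others with all 3 lay on chromosome 1 from 151253408 to 151255734, on chromosome 9 from 102860161 to 102862354 and on chromosome 22 from 19465970 to 19467913.

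**Figure D1:**
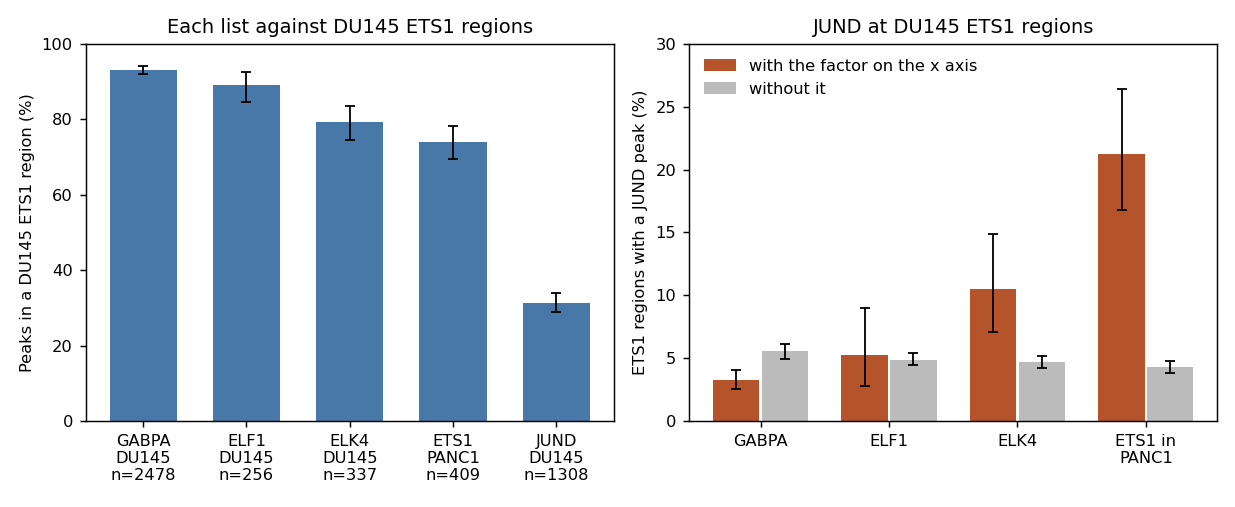
The left panel shows the percentage of peaks of each list that lie in a DU145 ETS1 region, with the number of peaks under each bar. The right panel shows the percentage of DU145 ETS1 regions that hold a JUND peak, among regions with (orange) and without (grey) a peak of the list on the x axis. Bars are shares of peaks or regions from 1 sample per list, and error bars are 95% Clopper-Pearson intervals. JUND peaks lay in ETS1 regions least often, at 31.4%, and the JUND share was lower at regions with GABPA (3.26%) and higher at regions shared with PANC1 (21.3%).

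With whole lists, JUND overlapped ETS1 less than the other ETS factors did. Lists shortened by width, at different lengths, put JUND (14.1%) above ELK4 (8.31%) and ELF1 (2.34%) and below GABPA (33.2%). Shortened by line order, also at different lengths, JUND was at 9.56%, ELK4 at 7.42%, ELF1 at 9.77% and GABPA at 49.5%. Of the JUND peaks, 31.4% (28.8 to 33.9%, 410 of 1308) lay in an ETS1 region, against a random mean of 0.775%, while 898 (68.6%) did not, and with peak centres within 200 bp the share was 14.6%. Of ETS1 regions, 4.89% (4.43 to 5.38%, 400 of 8183) held a JUND peak. The share of peaks with JUND was 2.42% for GABPA (1.85 to 3.11%), 3.91% for ELF1 (1.89 to 7.07%) and 5.94% for ELK4 (3.66 to 9.02%). Against ETS1 regions, the odds of JUND overlap were lower for GABPA (odds ratio 0.483, 0.3604 to 0.637, Fisher's exact test, two-sided, adjusted p = 7.17e-08). No difference was detected for ELF1 (0.791, 0.372 to 1.495, Fisher's exact test, adjusted p = 0.612) or for ELK4 (1.23, 0.732 to 1.96, adjusted p = 0.450). These lists differ in length and width, and sites present in both lists count in both rows of these tests. The second ETS1 list was then shortened by line order to the length of the other list, a setting chosen after seeing the data. ETS1 then had JUND at 10.9% against 3.91% for ELF1 (odds ratio 0.332, Fisher's exact p = 0.00364). Beside ELK4 it had JUND at 10.4% against 5.94% (0.545, exact p = 0.0480, both p unadjusted), with the direction of the ELK4 comparison turned. This cut keeps the first ETS1 lines but all lines of the other list. The whole second ETS1 list had JUND at 4.41%, so the cut itself raised the ETS1 share. It does not show more JUND at ETS1 than at ELF1 or ELK4. Lists shortened by width gave 0.112 for ELF1 and 0.256 for ELK4. That setting keeps the widest ETS1 regions, which meet JUND more easily than narrow windows do. Its values cannot be read as less JUND at ELF1 or ELK4 peaks. With 500 bp intervals, chosen after seeing the data, the odds ratios were 1.01 for ELF1 and 1.57 for ELK4. The second ETS1 list of windows alone gave 0.882 and 1.37. All intervals of these settings held 1. With the lists shortened by line order to the size of the shortest, neither difference was past the threshold (0.368 for ELF1, exact p = 0.221, and 0.618 for ELK4, p = 0.576).

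Among ETS1 regions, those with another ETS factor held JUND less often than those without. The shares were 3.74% (3.03 to 4.56%, 93 of 2489) and 5.39% (4.82 to 6.01%, 307 of 5694), an odds ratio of 0.681 (0.532 to 0.866, Fisher's exact test, two-sided, adjusted p = 0.00191). The intervals for GABPA and ELK4 lay on opposite sides of 1. With GABPA the JUND share was 3.26% against 5.53% without it (0.576, 0.440 to 0.746, exact test, adjusted p = 2.33e-05). With ELK4 it was 10.5% against 4.70% (2.39, 1.53 to 3.60, exact test, adjusted p = 2.14e-04), and with ELF1 5.26% against 4.88% (1.08, 0.546 to 1.95, adjusted p = 0.755). The difference by any other ETS factor was not past the threshold with peaks under 5 kb apart merged (0.890) or among the wider peaks (0.863). The same held for lists shortened by line order (0.596). Among lists shortened by width its direction turned (2.44), as did that of GABPA (2.41), but neither turned value was past the threshold. The GABPA difference was also not past it among the wider peaks (0.693). The ELK4 difference was lost with peak centres within 200 bp (1.23) and among the earlier lines of every list (1.41) and with lists shortened by width (1.55).

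The widest ETS1 regions with JUND and no other ETS factor included chromosome 11 from 65264430 to 65275740, chromosome 10 from 75668381 to 75678140 and chromosome 12 from 52624460 to 52633840. The first and second of these also held a PANC1 ETS1 peak. The widest with another ETS factor and no JUND included chromosome 19 from 13260202 to 13266660, with ELK4, GABPA and PANC1 ETS1 peaks, and chromosome 17 from 7140507 to 7146743, with GABPA alone.

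The last comparison concerned ETS1 in the second cell line. Of the PANC1 ETS1 peaks, 74.1% (69.6 to 78.3%, 303 of 409) lay in a DU145 ETS1 region, against a random mean of 0.798%, and 3.62% of DU145 ETS1 regions (3.22 to 4.04%, 296 of 8183) held a PANC1 peak. With peak centres within 200 bp the first share was 39.4%. The PANC1 list was concentrated on chromosome 6, which held 86 of its 409 peaks (21.0%) but 5.33% of the DU145 ETS1 regions (odds ratio 4.73, 3.61 to 6.14, Fisher's exact test, two-sided, adjusted p = 2.58e-24 over 28 tests). Of those 86 peaks, 76 lay between 26027183 and 30710795, in the densest 5 Mb window of PANC1 peaks on the chromosome, found by search in this same list. PANC1 peaks in this stretch overlapped DU145 ETS1 regions in 35.5% of cases (24.9 to 47.3%). Those elsewhere did so in 82.9% (78.4 to 86.8%, odds ratio 0.115, Fisher's exact p = 1.51e-15, unadjusted). The 76 peaks form 1 local cluster that was picked from these data, so this p overstates the evidence.

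**Figure D2:**
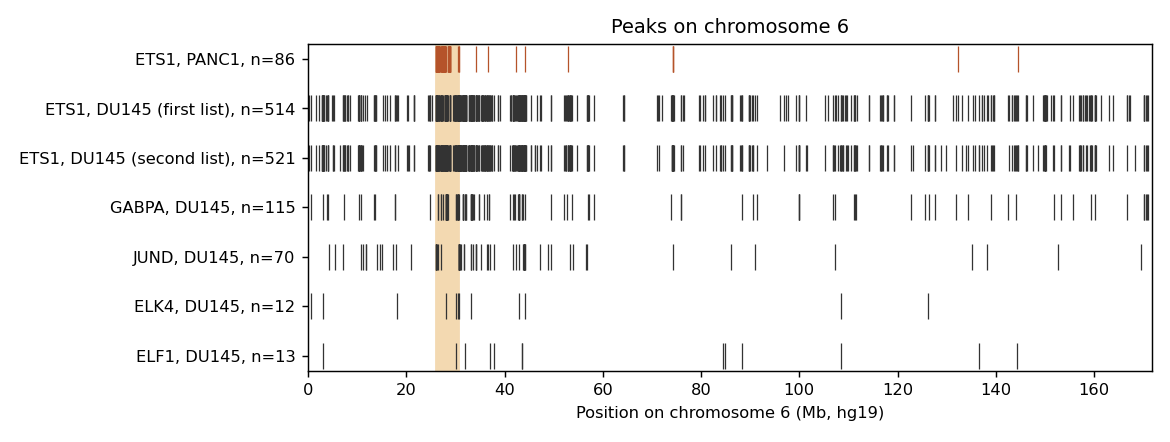
Positions of peak centres on chromosome 6 in Mb (hg19), with 1 row per peak list, 1 tick per peak and the number of peaks on the chromosome beside each name. The shaded band spans 26027183 to 30710795, where 76 of the 86 PANC1 ETS1 peaks of the chromosome lie. The 5 Mb window that starts at the first of these peaks holds 82 of 514 peaks of the first DU145 ETS1 list and 100 of 521 of the second.

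DU145 ETS1 regions shared with PANC1 held JUND more often than the rest. The shares were 21.3% (16.8 to 26.4%, 63 of 296) and 4.27% (3.84 to 4.74%, 337 of 7887), an odds ratio of 6.06 (4.42 to 8.22, Fisher's exact test, two-sided, adjusted p = 2.22e-23). For the other ETS factors no difference was detected, with 27.7% (22.7 to 33.2%) against 30.5% (29.5 to 31.6%) and an odds ratio of 0.872 (0.665 to 1.14, exact test, adjusted p = 0.450). Taken singly, after seeing the data, the odds ratio was above 1 for ELK4 (2.25, 1.33 to 3.62, exact test, adjusted p = 0.00294 over 10 pairs), while the intervals held 1 for GABPA (0.831, 0.626 to 1.09) and ELF1 (0.714, 0.257 to 1.60). At equal line order the interval held 1 for ELK4 (1.49, 0.919 to 2.43) and lay below 1 for GABPA (0.432, 0.324 to 0.575) and ELF1 (0.425, 0.186 to 0.974). The comparison of the 3 together depended on the setting. It was above 1 and past the threshold among the wider peaks (1.64) and among lists shortened by width (2.79). It was below 1 and past it within 5 equal groups of ETS1 regions by line order, pooled after seeing the data (Mantel-Haenszel odds ratio 0.460, 0.348 to 0.607), and among the earlier lines of every list (0.713).

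Taken as lists, PANC1 ETS1 peaks met a DU145 JUND peak in 13.0% of cases (9.86 to 16.6%, 53 of 409) and DU145 ETS1 regions in 4.89% (odds ratio 2.90, 2.09 to 3.95, Fisher's exact test, two-sided, adjusted p = 4.37e-09). They met a GABPA peak in 15.4% (12.0 to 19.3%) against 28.1% (0.465, 0.348 to 0.613, exact test, adjusted p = 1.45e-08). Sites shared by DU145 and PANC1 count in both rows of these tests. The JUND difference depended on which DU145 lines were used. The first 409 lines of the second DU145 ETS1 list, a set chosen after seeing the data, had JUND at 9.54% (6.87 to 12.8%), and the difference from PANC1 was then not past the threshold (odds ratio 1.41, 0.892 to 2.25, Fisher's exact p = 0.150). The same 409 lines had GABPA at 50.4%, with an odds ratio for PANC1 farther from 1 (0.180, 0.127 to 0.253). Earlier ETS1 lines hold both JUND and GABPA more often, and the PANC1 list was kept whole, so this cut raises the DU145 shares. Among lists shortened by width, which keep the widest ETS1 regions, the JUND odds ratio turned to 0.583 and that of GABPA was 0.945. Wide regions meet other lists more easily, so this turn cannot be read as less JUND at PANC1 peaks.

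**Figure D3:**
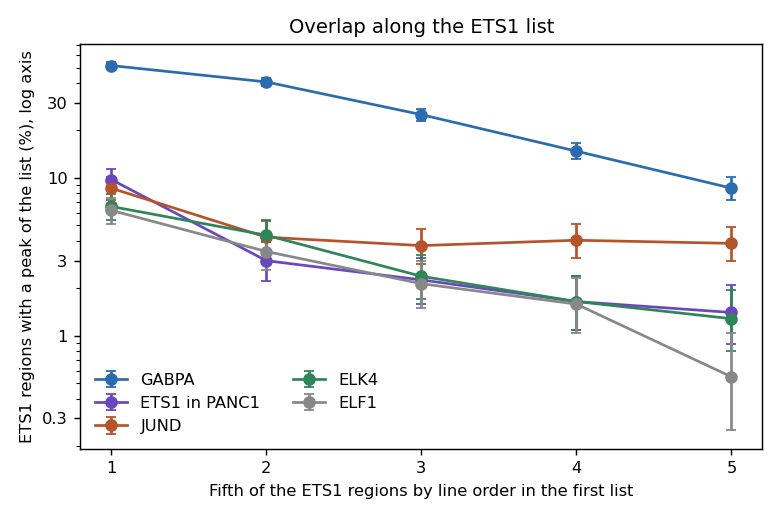
Percentage of DU145 ETS1 regions that hold a peak of each list (y axis, log scale), in 5 equal groups of the 8183 regions by line order in the first ETS1 list (x axis). Points are shares of 1636 or 1637 regions and error bars are 95% Clopper-Pearson intervals. GABPA fell from 51.5% in group 1 to 8.62% in group 5, while JUND was 8.61% in group 1 and between 3.73% and 4.22% in the others.

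The overlap with every other list was higher among the earlier lines of the ETS1 list. From group 1 to group 5 of the ETS1 regions by line order, the share with GABPA went from 51.5% to 8.62%, with ELF1 from 6.23% to 0.55%, with ELK4 from 6.60% to 1.28%, and with PANC1 ETS1 from 9.77% to 1.41%. JUND was at 8.61% (7.30 to 10.1%) in group 1 and at 3.85% (2.97 to 4.9%) in group 5. What the line order stands for is not given in the sources used here.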

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

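The tests at equal ETS1 line order of other ETS factors, together or singly, at regions shared with PANC1, with or without JUND, the test with 500 bp intervals for regions shared with PANC1, and the tests without the dense stretch of chromosome 6, were chosen after the results were seen. Differences between the PANC1 and DU145 ETS1 lists were tested for 24 chromosomes and 4 other lists with Fisher's exact test, two-sided, and 6 of the 28 tests passed after Benjamini-Hochberg adjustment. With 1 sample per line, each describes these lists, and sites shared by both lists count in both rows. Chromosome 6 took 21.0% of PANC1 peaks and 5.33% of DU145 regions (odds ratio 4.73). PANC1 peaks had JUND more often (2.90) and GABPA less often (0.465). Chromosome 4 held 0 of 409 PANC1 peaks, which allows a share of up to 0.733% by a floor of 3 counts, and 229 DU145 regions (odds ratio 0, upper bound 0.317, exact test, adjusted p = 1.62e-04). Chromosome 9 held 4 PANC1 peaks (0.201, exact test, adjusted p = 3.91e-04) and chromosome 5 held 7 (0.397, adjusted p = 0.0461). Without the dense stretch of chromosome 6, which lowers the share of every other chromosome, chromosomes 4 and 9 stayed past the threshold (exact test, adjusted p = 0.00172 and 0.00781), chromosome 5 did not (0.233), and chromosome 19 passed it (odds ratio 1.64, adjusted p = 0.0269).

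The concentration on chromosome 6 was the first pattern weighed. Extra copies of the whole chromosome in PANC1 would spread the peaks along it, but 88.4% (79.6 to 94.3%) of its 86 PANC1 peaks lay in one stretch of 5 Mb. The stretch was picked as the densest window of these peaks, and the intervals of the PANC1 shares do not allow for that search. High background in both lines would fill the stretch in DU145 as well. The highest share of any DU145 list there was 1.19%, against 18.6% (14.9 to 22.7%) in PANC1. But a share of the whole list shrinks as the list grows. The stretch held 82 and 100 peaks of the DU145 ETS1 lists, against 76 of PANC1. These were 15.95% and 19.19% of the chromosome 6 peaks of the DU145 lists. The comparison therefore cannot exclude background common to both lines. A gain of that stretch alone in PANC1, background in that line or in both, and ETS1 binding specific to PANC1 all stay open. They were untested, since the PANC1 input was not analysed here.

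The lower JUND share at ETS1 regions with other ETS factors was the second. Its odds ratio of 0.681 became 0.496 (0.385 to 0.639) at equal ETS1 line order and 0.608 with 500 bp intervals. Both checks are void as tests of a cause, since strong sites that enter every list and wide intervals would each raise the JUND share at these regions, and the outcomes named for them beforehand did not allow for that. Separate use of sites by AP-1 and GABPA stays open as untested, since it would take JUND ChIP after loss of GABPA to decide, and the thresholds of the JUND and GABPA lists stay open too, as does the loss of the call in some settings.

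The higher JUND share at ETS1 regions shared with PANC1 was the third. If earlier lines hold stronger ETS1 regions, which no source states, strong regions reaching both short lists should leave little or no association at equal line order. The odds ratio there was 5.19 (3.78 to 7.12), and with 500 bp intervals it was 5.08. But ETS1 regions with both PANC1 and JUND had a median width of 2365 bp, against 1273 bp for all ETS1 regions. The 500 bp intervals take width out of the overlap, but no setting compared regions of equal deposited width. The 5 groups are also coarse, since 18.75% of the first 256 ETS1 regions held a PANC1 peak, against 9.77% of group 1. Strength that varies within a group could therefore leave part of the association. Sites of high background that enter every list would also hold other ETS factors more often, and the first test of this, without regard to line order, decided nothing (0.914, 0.497 to 1.62). At equal line order, in tests added because the first decided nothing, the odds ratio was 0.352 (0.202 to 0.614), with 0.255 (0.138 to 0.473) for GABPA but 3.04 (1.502 to 6.15) for ELK4, and all regions shared with PANC1 had 0.460 (0.348 to 0.607), so the low value is not particular to those with JUND. Shared ETS1 and AP-1 sites in both lines stay open as a hypothesis that JUND ChIP in PANC1 would test. So do strength that the 5 groups by line order do not capture and the greater deposited width of these regions. Background that enters the ETS1, JUND and ELK4 lists but not that of GABPA also stays open.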

How the results depend on the processing

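The settings by line order, by 500 bp intervals and without chromosome 6 were chosen after seeing the data, and the others were planned. Over all settings, 292 values kept their direction and side of the threshold, 11 of them odds ratios that moved by over 1.5 times. A further 43 shares moved by over 1.5 times and 19 values reversed, 12 of these with neither value past the threshold. Significance was lost in 10 and gained in 5. Some of the 292 could not change, so this count overstates stability. Shifted placements leave each share as it was. Overlaps of the other lists with JUND do not depend on which DU145 ETS1 list is used. Every share stayed above its random placements (permutation p = 0.001, the smallest the placements can give). A p at its limit does not show how far the excess shrinks. With placements shifted by 10 to 100 kb, the excess over the random mean fell for every share. For JUND peaks in ETS1 regions it fell from 40.5 to 11.8 times, and for PANC1 ETS1 peaks from 92.8 to 22.6 times. The higher JUND share at ETS1 regions shared with PANC1 held in every setting that was run, with odds ratios from 4.34 to 34.6 and p-values up to 7.52e-04. The lower odds of JUND for GABPA than for ETS1 held wherever a value was had (0.122 to 0.669). Rankings by width say little in the 5 lists of nearly uniform windows. For the ETS1 regions they keep the widest, which meet other lists more easily than narrow windows do. The causes of these changes were not tested. No paired analysis was possible because each group has 1 sample. With the depth of every list unknown, a missing overlap cannot be read as missing binding.

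With the lists of each comparison shortened by width to the shortest among them, so that shares below are at different lengths, shares in ETS1 regions were 2.34% for ELF1, 8.31% for ELK4, 33.2% for GABPA, 14.1% for JUND and 19.1% for PANC1. ETS1 regions then held ELK4 at 8.01%, JUND at 13.2% and PANC1 at 17.4%, and JUND met 1.56% of ELF1, 2.67% of ELK4 and 7.82% of PANC1 peaks. Odds ratios of JUND against ETS1 were 0.112 for ELF1, 0.256 for ELK4 and 0.583 for PANC1, with GABPA at 0.945 for PANC1. Within ETS1 regions JUND had 7.51 by ELF1, 1.55 by ELK4, 2.41 by GABPA and 2.44 by any other ETS factor, and other ETS factors had 2.79 by PANC1.

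Shortened in the same way by line order, shares in ETS1 regions were 9.77% for ELF1, 7.42% for ELK4, 49.5% for GABPA, 9.56% for JUND and 18.6% for PANC1. ETS1 regions held ELF1 at 9.77%, ELK4 at 7.42%, GABPA at 49.3%, JUND at 8.94% and PANC1 at 17.8%. JUND met 1.17% of ELF1, 2.97% of ELK4 and 7.09% of PANC1 peaks. Odds ratios of JUND against ETS1 were 0.368 for ELF1 (Fisher's exact p = 0.221) and 0.618 for ELK4 (p = 0.576). The odds ratio of JUND was 0.596 by other ETS factors and 1.34 for PANC1 against DU145.

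With centres within 200 bp, 52.2% of ELK4, 14.6% of JUND and 39.4% of PANC1 peaks lay at ETS1 regions, which held ELK4 at 2.15%, JUND at 2.33% and PANC1 at 1.97%. JUND met 2.67% of ELK4, 1.57% of GABPA and 7.34% of PANC1 peaks, and the odds ratio of JUND by ELK4 was 1.23 and by ELF1 0.984, with ELF1 against ETS1 at 1.52.

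Among the wider peaks, shares in ETS1 regions were 48.4% for ELF1, 44.4% for ELK4, 47.2% for GABPA and 18.4% for JUND, and JUND met 2.34% of ELF1 and 1.29% of GABPA peaks. Odds ratios of JUND were 0.693 by GABPA, 0.769 by ELF1 and 0.863 by other ETS factors, and other ETS factors had 1.64 by PANC1.

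Among the earlier lines, ETS1 regions held JUND at 3.09% and PANC1 at 5.76%, 19.6% of JUND peaks lay in ETS1 regions and JUND met 0.968% of GABPA peaks. The odds ratio of JUND was 1.41 by ELK4, 0.709 by ELF1 and 1.28 for ELF1 against ETS1, and that of other ETS factors by PANC1 was 0.713. Pooled within 5 equal groups of ETS1 regions by line order, the latter was 0.460 and JUND by ELF1 had 0.854. Other ETS factors by PANC1 had 1.08 with the first ETS1 list alone and 1.14 with the union, and JUND by ELF1 had 0.804 with the second alone. With 500 bp intervals, JUND had 0.823 by ELF1 and 1.01 for ELF1 against ETS1. With peaks under 5 kb apart merged, JUND by other ETS factors had 0.890. Against the second ETS1 list shortened to equal length, odds ratios of JUND were 0.332 for ELF1, 0.545 for ELK4 and 1.41 for PANC1. This cut keeps the earlier lines of the DU145 ETS1 list, where JUND is more frequent, and so raises its share.

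No odds ratio was computed for JUND at GABPA against ETS1 with lists shortened by width, or for JUND by ELK4 and by GABPA with lists shortened by line order, since a cell was 0. Placements matched on transcription start sites, and all alternatives for promoters, motifs and gene lists, were not run.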

Other observations

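The tests in this part were chosen after the results were seen. ELK4 and GABPA differed in how they met JUND at ETS1 regions in the main setting. Over all ETS1 regions, the ELK4 difference was lost with centres within 200 bp (1.23) and among the earlier lines (1.41). That of GABPA turned among lists shortened by width (2.41), where it was not past the threshold. Where GABPA was absent, ETS1 regions with ELK4 held JUND at 16.5% and those without ELK4 at 5.34% (odds ratio 3.50, 1.89 to 6.12, Fisher's exact test, two-sided, p = 6.90e-05, 97 regions with ELK4). Where ELK4 was absent, regions with GABPA held JUND at 2.95% and those without at 5.34% (0.539, 0.403 to 0.713, exact p = 3.73e-06). ELK4 shared 20 ETS1 regions with PANC1 where 9.62 would follow from independence (odds ratio 2.25, 1.33 to 3.62, exact test, adjusted p = 0.00294 over 10 pairs), but both favour the earlier ETS1 lines, and at equal line order the interval held 1 (1.49, 0.919 to 2.43). Of the ELK4 peaks, 53 (15.7%) lay in neither ETS1 list, against 2.66% of GABPA peaks. One of them, on chromosome 5 from 137827520 to 137828020, was on line 3 of the ELK4 list and met no other list.

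Most ETS1 regions, 5218 of 8183 (63.8%), met none of the other 5 lists. The longest of these lists holds 2478 peaks, so many regions would meet none in any case. GABPA peaks on earlier lines lay in ETS1 regions more often than those on later lines, at 98.2% against 88.0% (odds ratio 7.56, 4.77 to 12.5, Fisher's exact test, two-sided, adjusted p = 2.80e-25 over 4 lists). For ELK4 the shares were 75.2% and 83.3% (0.606, exact test, adjusted p = 0.107).

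Of all JUND peaks, 590 of 1308 (45.1%) lay within 10 kb of an ETS1 region, 410 of them in one, against 7.25% of random placements. Within 100 kb the shares were 75.8% and 34.4%. Placements along whole chromosomes ignore that binding sites cluster, so both random shares are a low baseline. Peak centres of the second ETS1 list lay at a median of 72 bp from overlapping GABPA centres (quartiles 28 and 142 bp, 2285 pairs) and at 134 bp from JUND centres (60.2 and 253 bp, 410 pairs). JUND intervals are wider, and for the 53 pairs with JUND intervals no wider than the windows of the other lists the median was 100 bp (43 and 172 bp).

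The peak on line 1 of the ELF1 list, on chromosome 21 from 9825862 to 9826362, also overlapped an ELK4 peak and a peak of the first ETS1 list but none of the second. No filter for regions of high background was applied here, so this overlap alone cannot be read as shared binding. Within the dense stretch of chromosome 6, neighbouring PANC1 ETS1 peaks lay a median of 17515 bp apart.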
